A study of Homo sapiens with 8 samples.

How the data were processed

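RNA was measured in OCI-AML3 cells, an established human acute myeloid leukaemia line, by polysome profiling followed by RNA sequencing. Per the labels' protocols, cells had been infected with lentiviral short hairpins, either a control hairpin or a hairpin against FBL. FBL encodes fibrillarin, the nucleolar 2'-O-methyltransferase of box C/D small nucleolar ribonucleoproteins. Cells were treated with cycloheximide at 100 µg/mL for 15 min, which holds ribosomes on their mRNAs. Cells were lysed in 400 µL of buffer. Of the cleared lysate, 100 µL was kept as input RNA and 290 µL was loaded on a sucrose gradient from 10% to 50%, from which 14 fractions were collected. Which of these fractions were combined as polysome RNA is not given in the sources used here.

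The labels part the libraries into 4 groups of 2 each, 8 libraries in all: input control, input knockdown, polysome control and polysome knockdown. The genotype label reads WT for the libraries called control here, while the protocols name a control hairpin. It reads FBL knockdown for the libraries called knockdown. The sample titles read CT for the WT libraries and U for the FBL knockdown libraries. Library numbers 1 and 2 come from the sample titles. The labels do not say whether the libraries of a group came from separate infections or cultures, so the p-values measure the spread between these libraries, which may in part be technical.

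The deposited files hold raw read counts per gene, which the authors made, per the submitters' processing notes, with Trimmomatic 0.38, Bowtie2 (version not given in the sources used here) and HTSeq 0.11.2 on the GRCh38 genome. The annotation release, the sequencing layout and the strand setting are not given in the sources used here. Bowtie2 does not place reads across introns, so reads over exon junctions may be lost or moved to processed pseudogenes. Without a strand setting, reads of overlapping and antisense genes cannot be told apart. The counts were not normalized before deposit. Each file lists 58395 genes, of which 58275 identifiers are in GENCODE v29 and 120 are not. GENCODE v29 gave gene types, positions, exon lengths and GC content on GRCh38, and symbols came from a table of current names.

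Counts assigned to genes ranged from 22.2 mega-counts (M) in polysome knockdown 2 to 43.1 M in input knockdown 2. The lines of the files that name no gene stayed out of library sizes and tests. Together they held 13.2% to 15.0% of all reads listed, with 5.72% to 6.79% ambiguous between genes and 2.91% to 5.45% outside any gene. Libraries of a group were compared with a chi-square of their counts over genes. It came to 22.1 to 48.7 per degree of freedom, more than repeat sequencing of a single library would give. This does not tell separate cultures from repeat preparations of the same cells, and each library was counted as a sample because the labels list it as such.

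All comparisons were fitted with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test on the deposited counts. Normalization was TMM and low counts were removed with filterByExpr, which left 16503 genes. The 8 libraries shared a single model with a term for each of the 4 groups, which left 4 residual degrees of freedom. Sharing was chosen because each group holds only 2 libraries. It assumes that a gene varies alike in input and polysome libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Levels are CPM after TMM, and log2 fold changes are given with their standard error (SE). All changes are relative to the other genes of a library: a change shared by the whole transcriptome, such as an overall loss of polysomes, would not be seen.

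The comparisons fixed before the data were examined were knockdown against control in input RNA, the same in polysome RNA, the difference between these changes (an interaction term, which measures a change in polysome association), and polysome against input RNA in control libraries. The comparison of polysome with input RNA in the libraries labelled knockdown was added after the FBL counts had been seen. Also fixed beforehand were 28 gene lists. They were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, and again with an estimated correlation. With an estimated correlation the test also rests on the few residual degrees of freedom of the fit. A call can then be lost without correlated genes. With the lysate as a block in control libraries, respiratory chain subunits went from p = 1.1e-14 to 0.017 (camera) at an estimated correlation of 0.010. The fry test served as a test of each list on its own. Lists needed at least 5 measured members.

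The genes named in the text follow a rule fixed beforehand. FBL is always named. In each comparison fixed beforehand the 6 largest increases and 6 largest decreases at an adjusted p under 0.05 are named, given a mean of at least 10 CPM in the higher group, no overlap between the libraries of the groups, a symbol and no pseudogene annotation. For each list that passes camera, the 2 called members with the smallest p are added. The added comparison in libraries labelled knockdown carries the genes named for polysome against input RNA in control libraries. Other genes are said to be chosen after their values were seen.

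Input and polysome RNA with the same title number came, per the labels' protocols, from a single cleared lysate. This was checked by the correlation over 8159 genes of the number 1 minus number 2 difference, which was 0.31 between input and polysome in the control groups and 0.36 in the knockdown groups. Between input and polysome groups of different labels, which share no lysate, it was 0.27, so most of this correlation is not specific to the lysate. Fits with the lysate as a block are therefore given beside a polysome against input result where they change it. Between control and knockdown, libraries share only a number.

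Alternatives planned beforehand were relative log expression and upper quartile normalization, DESeq2 1.42.0, limma-voom, no filter, a mean count of at least 10, removal of mitochondrially encoded genes and the 20 most abundant genes, a fit of only the 4 libraries compared, replicate blocks, and leaving out each library in turn. Added after seeing the data were a correction for GC content and exon length, in which a loess curve for each library entered the model as an offset, the same with a replicate block (number or lysate), an estimated correlation in the fit with the lysate block, and a filter at a mean of 10 CPM.

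The fits were tested on simulated counts with real means, library sizes and dispersions and 200 changed genes. For polysome RNA, 27% of genes changed 2-fold and 55% of genes changed 4-fold were recovered among 15598 genes tested, with 5 false calls. Among changed genes with a mean of at least 10 CPM these shares were 50.9% and 98.0%. For input RNA they were 63.8% and 100%, with 2 false calls, and for the interaction 29.5% and 90.6%, with 4 false calls. For polysome against input in control libraries they were 67.4% and 97.7%, with 10 false calls. A GC trend put into simulated counts (Spearman correlation 0.63) fell to 0.0026 with the correction.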

Results

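The series measured the transcriptome and the polysome-bound RNA of OCI-AML3 leukaemia cells labelled as with or without knockdown of FBL. Libraries of input RNA from the cleared lysate and of RNA from polysome fractions were made from cells labelled control or knockdown, with 2 libraries in each of the 4 groups. Gene counts in mega-counts (M) came to 36.6 M and 33.2 M in input control, 30.8 M and 43.1 M in input knockdown, 38.5 M and 40.8 M in polysome control, and 38.5 M and 22.2 M in polysome knockdown. Input libraries had reads from 18323 to 18440 genes and polysome libraries from 14344 to 15910. Of genes averaging at least 100 reads in the input libraries, 14 to 103 had no read in a given polysome library, with the most in the shallowest, polysome knockdown 2. Polysome libraries were also poorer in mitochondrial ribosomal RNA, at 0.0426% to 0.102% of gene counts against 1.25% to 1.52% in input.

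The targeted gene was examined first. FBL (ENSG00000105202, chromosome 19: 39834458 to 39846414 on GRCh38, GENCODE v29) was not lower in the libraries labelled knockdown. In input RNA its level was 169 ± 114 CPM in control and 168 ± 119 CPM in knockdown (SD, n = 2 each), a log2 fold change of -0.01 (SE 0.69, adjusted p = 1, edgeR). In polysome RNA the levels were 331 ± 236 and 332 ± 236 CPM, a log2 fold change of 0.01 (SE 0.69, adjusted p = 1). The large SDs came from the library numbers. FBL stood at 250 CPM in input control 1, 253 CPM in input knockdown 1, 498 CPM in polysome control 1 and 499 CPM in polysome knockdown 1. In the libraries numbered 2 it stood at 88.1, 84.2, 163 and 165 CPM in the same order, which is 64.8% to 67.2% lower within each group. With the library number also in the fit, FBL differed between the labels by a log2 fold change of -0.01 (SE 0.05, mean of both fractions). That fit counts the input and polysome libraries of a single lysate as separate samples, so its SE may be too small. The number is not a treatment in the labels, and no library was moved to another group. The groups are therefore called labelled knockdown and labelled control, and every direction below is drawn from labels that the FBL counts do not bear out.

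**Figure D1:**
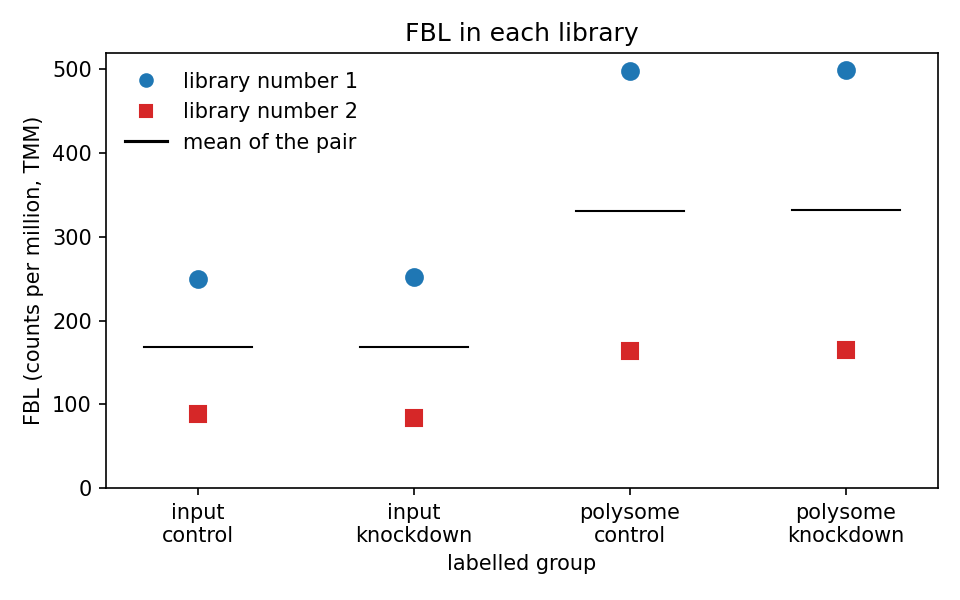
FBL level in CPM (TMM) in each of the 8 libraries, by labelled group, with circles for libraries numbered 1, squares for libraries numbered 2 and a line at the mean of each pair. The labelled control and labelled knockdown means are nearly equal (169 and 168 CPM in input, 331 and 332 CPM in polysome RNA), while each number 2 library lies 64.8% to 67.2% below its number 1 partner.

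Knockdown against control in input RNA asks which transcripts change in abundance. No gene was called. Among the genes with the smallest p, these, chosen after their values were seen, were higher in the libraries labelled knockdown: IFITM3, an interferon-induced membrane protein, at 952 ± 12.2 against 645 ± 3.07 CPM, the monocyte chemokine CCL2 at 147 ± 2.87 against 80.3 ± 8.39 CPM, and the macrophage scavenger receptor MARCO at 39.0 ± 7.05 against 16.8 ± 0.59 CPM (SD, n = 2 each). Each had an adjusted p of 0.198, the smallest of the comparison. IFITM3 has close paralogs, so its count is uncertain. With edgeR, 744 of 16503 genes had an unadjusted p under 0.05, where evenly spread p-values would give 825. Among genes with a mean of at least 10 CPM it was 669 of 8159, where they would give 408. Parting the same input libraries by number gave 323 genes and the crossed parting 25, with label-following differences left in the spread. A fit of the 4 input libraries alone gave 1619 of 15543 genes by label. The 825 is therefore a rough baseline, and 744 does not show an absence of differences. DESeq2 called 76 genes and limma-voom 3. A fit with the library number as a block called 66, although across labels the libraries share only a number.

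Several gene lists lay to one side in input RNA when genes were taken as nearly independent (camera, preset correlation). Nuclear-encoded respiratory chain subunits had a median log2 fold change of 0.23 over 74 measured genes, glycolysis genes 0.26 over 22, myeloid differentiation genes 0.22 over 41, large-subunit ribosomal proteins 0.16 over 47 and small-subunit ribosomal proteins 0.11 over 32. Proteasome subunits had a median of 0.14 and interferon-stimulated genes 0.10. On the lower side were large-subunit pre-rRNA processing factors (-0.19 over 52 genes), small-subunit processing factors (-0.15 over 50), MYC targets (-0.17 over 57), snoRNA host genes without a long reading frame (-0.15 over 19), cholesterol synthesis genes (-0.11), mRNAs reported to carry internal ribosome entry sites (-0.08) and p53 targets (-0.24). These 14 lists had adjusted p from 5.4e-14 to 0.0045, and none held with an estimated correlation, where the adjusted p ranged from 0.174 for glycolysis to 0.687 for p53 targets. In the fry test glycolysis genes passed (adjusted p = 0.046) and no other list did. No member of any list was called over all genes tested. Adjusted over the list alone, 7 myeloid genes were higher and 2 lower, and 6 glycolysis genes were higher. Erythroid and megakaryocyte markers (6 measured) and lymphoid markers (9 measured), which stand for other blood cell types, did not pass, with adjusted p of 0.734 and 0.273. The p53 list was at a median of 0.10 without input control 2, and its adjusted p was then 0.088.

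Knockdown against control in polysome RNA puts the same question to ribosome-bound transcripts. In the libraries labelled knockdown, 41 genes were higher and 104 lower. Among the largest increases, CCL2 rose to 83.8 ± 5.47 from 32.4 ± 0.243 CPM (log2 fold change 1.37, SE 0.13, adjusted p = 0.013), the matrix metalloproteinase MMP9 to 42.4 ± 4.92 from 18.2 ± 0.132 CPM, the lipopolysaccharide co-receptor CD14 to 58.9 ± 9.06 from 26.6 ± 5.57 CPM, and FCER1G, the shared signalling chain of Fc receptors, to 123 ± 22.4 from 56.4 ± 12.4 CPM (SD, n = 2 each). SMIM30, a small membrane protein, and GTSF1, a zinc-finger protein of the piRNA pathway, rose by log2 1.20 (SE 0.19) and 1.10 (SE 0.18). All of these had adjusted p from 0.013 to 0.041.

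Among the largest decreases, CLSPN, the checkpoint mediator claspin, fell by 3.20 on the log2 scale (SE 0.53, adjusted p = 0.036), but its control libraries were far apart at 42.5 and 155 CPM, against 13.7 and 7.52 CPM in knockdown, and without polysome control 2 its change was -1.99 (adjusted p = 0.125). DBF4, the activator of the replication kinase CDC7, fell to 3.40 ± 1.61 from 11.2 ± 2.33 CPM, and TERT, the catalytic subunit of telomerase, to 13.7 ± 0.577 from 35.7 ± 10.4 CPM. The list of DNA replication and G1/S genes did not pass (median 0.00 over 48 genes, 1 lower, adjusted p = 0.980). The zinc transporter SLC30A5 (log2 fold change -1.57, SE 0.30), the glycosyltransferase C1GALT1 (-1.34, SE 0.24) and the Golgi pH regulator GPR89A (-2.48, SE 0.42) also fell, at adjusted p from 0.036 to 0.050. GPR89A has a near-identical copy, so its count is uncertain. In input RNA the same 6 genes had log2 fold changes from -0.41 to -0.04, none of them called. The difference between the polysome and input change passed for none of the 6 without a block, and for CLSPN with the lysate as a block (-2.69, adjusted p = 0.026).

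By list, 4 of 41 myeloid genes rose in polysome RNA (CD14, FCER1G, AIF1 and, chosen after its value was seen, FCGR1A) and 1 fell, the transcription factor IRF8, also chosen after its value was seen (log2 fold change -0.62, SE 0.11, adjusted p = 0.036). AIF1, a calcium-binding protein of macrophages, reached 538 ± 53.2 from 326 ± 8.38 CPM. FCGR1A (0.69, SE 0.13) has near-identical copies and is uncertain. The list's median was 0.37 (camera adjusted p = 5.7e-06, but adjusted p = 0.395 with an estimated correlation), and 11 members rose and 1 fell when adjusted over the list alone. Of 74 respiratory chain subunits, NDUFB4 (log2 fold change 0.71, SE 0.13) and COX5A (0.95, SE 0.18) rose, and 17 rose and 3 fell when adjusted over the list alone (median 0.20, adjusted p = 1.3e-09, and adjusted p = 0.377 with an estimated correlation). Of 38 interferon-stimulated genes, IFIT1 (0.55, SE 0.10) and IFI44 (0.72, SE 0.13) rose (median 0.22, adjusted p = 5.7e-06, and adjusted p = 0.406 with an estimated correlation). Adjusted over the list alone, 3 interferon-stimulated genes rose.

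Large-subunit pre-rRNA processing factors lay on the lower side, with 3 of 52 called and 9 lower when adjusted over the list alone. NOC2L fell to 73.6 ± 0.138 from 129 ± 3.72 CPM and SURF6 to 115 ± 2.96 from 191 ± 14.4 CPM, both nucleolar proteins, and MYBBP1A, a nucleolar MYB-binding protein chosen after its value was seen, had a log2 fold change of -0.67 (SE 0.12, adjusted p = 0.041). The list's median was -0.20 (adjusted p = 0.0092, and adjusted p = 0.568 with an estimated correlation). Among ribosomal proteins only RPL14 was called, at 789 ± 94.9 against 508 ± 11.4 CPM, although 7 large-subunit members were higher and 4 lower when adjusted over the list alone. The large-subunit list had adjusted p = 0.024 and the small-subunit list 0.0057, and both had adjusted p = 0.563 with an estimated correlation. Glycolysis genes (median 0.27), proteasome subunits (0.24) and mitochondrial ribosomal proteins (0.06) passed on the higher side, and p53 targets (-0.54) and mRNAs reported to carry internal ribosome entry sites (-0.29) on the lower, with no member called in any of the 5. With an estimated correlation all 5 calls were lost, at adjusted p from 0.377 to 0.568. In the fry test, glycolysis genes (adjusted p = 0.033) and lymphoid markers (0.021) passed in polysome RNA and no other list did. Adjusted over the list alone, 9 glycolysis genes and 10 proteasome subunits were higher and none of either lower. Lymphoid markers moved with the label too: their median over 9 genes was 0.74, with no gene called (adjusted p = 0.0074, and adjusted p = 0.377 with an estimated correlation). Erythroid and megakaryocyte markers, 6 genes, had a median of 0.86 (adjusted p = 0.192).

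The number of polysome calls changed with the fit. DESeq2 called 1203 genes and limma-voom 297. With the library number as a block 1053 were called, with all 145 genes among them. Upper quartile normalization turned the split to 53 higher and 48 lower, relative log expression gave 47 and 76, and a filter at a mean of 10 CPM gave 194 and 132. The total of 145 genes became 63 without polysome control 1, 0 without polysome control 2, 1455 without polysome knockdown 1 and 41 without polysome knockdown 2. It became 38 and 44 without input control 1 or 2, and 10 and 5 without input knockdown 1 or 2. A fit of the 4 polysome libraries alone called 0 genes and the correction for GC content and length also called 0, with all 20 genes picked by the fixed rule keeping their sign in each. In that fit of 4 libraries 1582 of 14444 genes had an unadjusted p under 0.05 (edgeR), from 2987 of 16503 in the main fit. The 145 calls therefore rest on a spread shared with the input libraries.

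**Figure D2:**
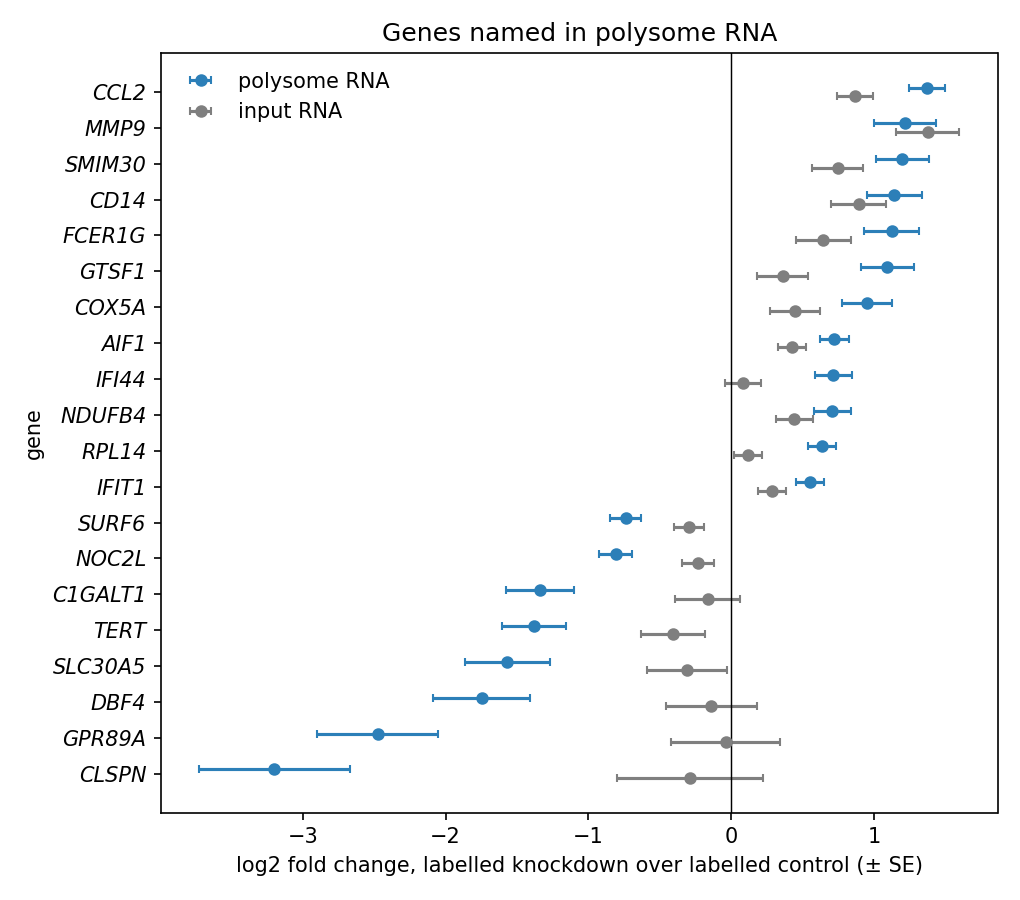
Log2 fold change of labelled knockdown over labelled control, with its SE, for the 20 genes named in polysome RNA (blue) and the same genes in input RNA (grey), n = 2 libraries per group. CCL2 changed by 1.37 in polysome and 0.87 in input RNA, while CLSPN changed by -3.20 and -0.29.

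The difference between the polysome and the input change asks whether the label went with a change in polysome association. No gene was called, and the smallest adjusted p was 0.756 (edgeR). An unadjusted p under 0.05 was found for 1046 of 16503 genes, where evenly spread p-values would give 825. DESeq2 called 10 genes and limma-voom 0. With the lysate as a block, 9 genes were called, all lower in polysome relative to input RNA in the libraries labelled knockdown. Chosen after their values were seen, they included the ribosomal proteins RPL37 (log2 difference -0.57, SE 0.08, adjusted p = 0.0043) and RPL36 (-0.52, SE 0.09, adjusted p = 0.040), the lactate transporter SLC16A3 (-0.76, SE 0.13, adjusted p = 0.032), the phosphatase activator PTPA (-0.64, SE 0.12, adjusted p = 0.046), CLSPN (-2.69, SE 0.45, adjusted p = 0.026) and the noncoding RNAs MIR142HG (-1.42, SE 0.13, adjusted p = 3.0e-05) and NEAT1 (-0.93, SE 0.13, adjusted p = 0.0044). RPL37 went from 2324 ± 90.3 to 3029 ± 78.0 CPM in input RNA and from 1931 ± 143 to 1693 ± 17.6 CPM in polysome RNA (SD, n = 2 each). SEC62, of the protein translocation channel, had a log2 difference of -0.96 (SE 0.21) at an adjusted p of 0.756.

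No gene list passed for this difference without the block, the smallest adjusted p being 0.166. With the lysate block, p53 targets (median -0.31, adjusted p = 0.017) and proteasome subunits (0.10, adjusted p = 0.030) passed. Both had adjusted p = 0.662 with an estimated correlation in the blocked fit. That was the smallest value of any list there, at fewer residual degrees of freedom. Large-subunit ribosomal proteins had a median of -0.04, and 1 member was higher and 7 lower when adjusted over the list alone. FBL had a log2 difference of 0.01 (SE 0.98). Over all alternatives of filter, scaling, tool and library left out, this difference gave between 0 and 55 calls.

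Polysome against input RNA in the libraries labelled control gives the background to these comparisons. Of 16503 genes, 2720 were higher in polysome RNA and 2090 lower. Lists of nuclear-encoded mitochondrial and energy metabolism genes lay on the higher side, in calls that were lost with an estimated correlation (respiratory chain adjusted p = 0.176, mitochondrial ribosomal proteins 0.087, glycolysis 0.263). Of 74 respiratory chain subunits 50 rose and 6 fell, with a median log2 fold change of 0.78, and NDUFB7 reached 661 ± 24.8 from 209 ± 7.63 CPM (SD, n = 2 each) and NDUFS6 rose by log2 1.25 (SE 0.09). Of 77 mitochondrial ribosomal proteins 32 rose and 5 fell (median 0.42), among them MRPL41 at 819 ± 7.29 against 242 ± 4.37 CPM and MRPL55 at 386 ± 14.6 against 140 ± 3.68 CPM. Glycolysis genes rose in 13 of 22 cases and fell in 1 (median 0.46), with GAPDH at 3998 ± 163 against 1807 ± 70.6 CPM and TPI1 at 3019 ± 31.9 against 1581 ± 45.3 CPM, both of which have pseudogenes that may share reads. Of 31 proteasome subunits 16 rose and 4 fell (median 0.59), with PSMC3 at log2 1.35 (SE 0.09) and PSMB7 at 1.32 (SE 0.09).

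The camera test passed for these lists with adjusted p of 8.2e-18 for the respiratory chain, 5.2e-07 for mitochondrial ribosomal proteins, 9.1e-06 for the proteasome and 1.5e-04 for glycolysis. With an estimated correlation all 4 calls were lost, the proteasome at adjusted p = 0.263. Mitochondrial ribosomal proteins passed the fry test (adjusted p = 6.7e-04). MYC targets passed camera too, with 24 of 57 higher and 9 lower (median 0.42, adjusted p = 0.0026). They had adjusted p = 0.850 with an estimated correlation and 0.055 in the fry test. The pre-rRNA processing factor RRP9 (log2 fold change 1.25, SE 0.11) and the mitochondrial RNA-binding protein TBRG4 (1.07, SE 0.10) led that list. Its call was lost without input control 2 (median 0.28) and with GC and length correction (0.12, adjusted p = 0.089), though not when the lysate was a block in that fit (0.12, adjusted p = 0.026). Adjusted over the list alone, the numbers higher and lower were 52 and 7 for the respiratory chain, 36 and 5 for mitochondrial ribosomal proteins, 14 and 1 for glycolysis, 16 and 5 for the proteasome, and 26 and 13 for MYC targets.

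Lists of mitochondrially encoded mRNAs, snoRNA host genes and nuclear-retained RNAs lay on the lower side in polysome libraries. All 13 mRNAs encoded by the mitochondrial genome fell (median log2 fold change -3.27, adjusted p = 2.5e-13, and adjusted p = 0.344 with an estimated correlation). MT-ND2 stood at 210 ± 27.3 against 4771 ± 394 CPM, and MT-ND4 and MT-ATP6 had log2 fold changes of -4.46 (SE 0.52) and -4.42 (SE 0.48). The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 stood at -4.41 (SE 0.44) and -4.17 (SE 0.33). Nuclear copies of mitochondrial sequence may share some of these reads. Of 19 snoRNA host genes without a long reading frame 14 fell and 1 rose (median -0.85, adjusted p = 2.1e-13). This call held with an estimated correlation, at adjusted p = 0.031, and in the fry test, at adjusted p = 3.1e-04. With the lysate as a block and an estimated correlation it had adjusted p = 0.409. No list had a smaller value in that fit, which has fewer residual degrees of freedom, so this loss decides nothing. SNHG3 was at 16.4 ± 0.929 against 284 ± 15.6 CPM and SNHG5 at 44.0 ± 2.06 against 244 ± 0.807 CPM. Nuclear-retained long noncoding RNAs fell in 5 of 9 cases (median -1.03, adjusted p = 1.5e-04, and adjusted p = 0.263 with an estimated correlation), with NEAT1 at 75.7 ± 13.4 against 548 ± 138 CPM and NORAD, which is largely cytoplasmic, at 17.9 ± 2.53 against 69.5 ± 6.66 CPM. RN7SL2, a signal recognition particle RNA gene with many near-identical copies, fell by 4.69 (SE 1.03) from 21.6 ± 2.53 CPM and is uncertain. Adjusted over the list alone, 13 mitochondrially encoded mRNAs and 14 snoRNA hosts fell, and 6 of the nuclear-retained RNAs fell and 1 rose.

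mRNAs of the cytosolic translation machinery went both ways. Large-subunit ribosomal proteins rose in 17 and fell in 17 of 47 cases (median 0.08, mean -0.01, adjusted p = 0.955), and small-subunit proteins rose in 15 and fell in 7 of 32 (median 0.25, adjusted p = 0.070). The small-subunit proteins passed the fry test (adjusted p = 0.043) and the large-subunit proteins did not (0.931). Of 47 translation factors 14 rose and 13 fell (median -0.13, adjusted p = 0.779). Adjusted over the list alone these numbers were 18 and 17, 15 and 7, and 15 and 16.

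The largest single increases in polysome RNA were CLSPN (log2 fold change 3.96, SE 0.55), LKAAEAR1 (2.06, SE 0.33), ZNHIT6 of the box C/D assembly pathway (1.99, SE 0.60), the orphan receptor GPR153 (1.88, SE 0.33), the elongin subunit ELOB (1.84, SE 0.18) and PPP1R3G, a regulator of glycogen synthesis (1.83, SE 0.26), at adjusted p from 6.2e-05 to 0.030. The CLSPN value came from polysome controls at 42.5 and 155 CPM, and without polysome control 2 it was 2.73 (adjusted p = 0.0014). The ZNHIT6 value rested on polysome control 2, at 43.0 against 8.39 CPM in polysome control 1. Without that library its change was 0.37 and was not called. FBL itself had a log2 fold change of 0.97 (SE 0.70, adjusted p = 0.348), and with the lysate as a block 0.94 (adjusted p = 1.7e-08). The lysate block also brought ATF4 and integrated stress response genes past the threshold (median 0.19, adjusted p = 0.038, from 0.100 without it, with a mean of -0.01). With an estimated correlation in the blocked fit, where no list passed, they had adjusted p = 0.409. The counts fell to 1748 higher and 1367 lower without input control 1, to 1792 and 1434 without input control 2, and to 1327 and 1109 with GC and length correction, which kept 1861 of the 4810 calls, 1842 of them in the same direction.

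**Figure D3:**
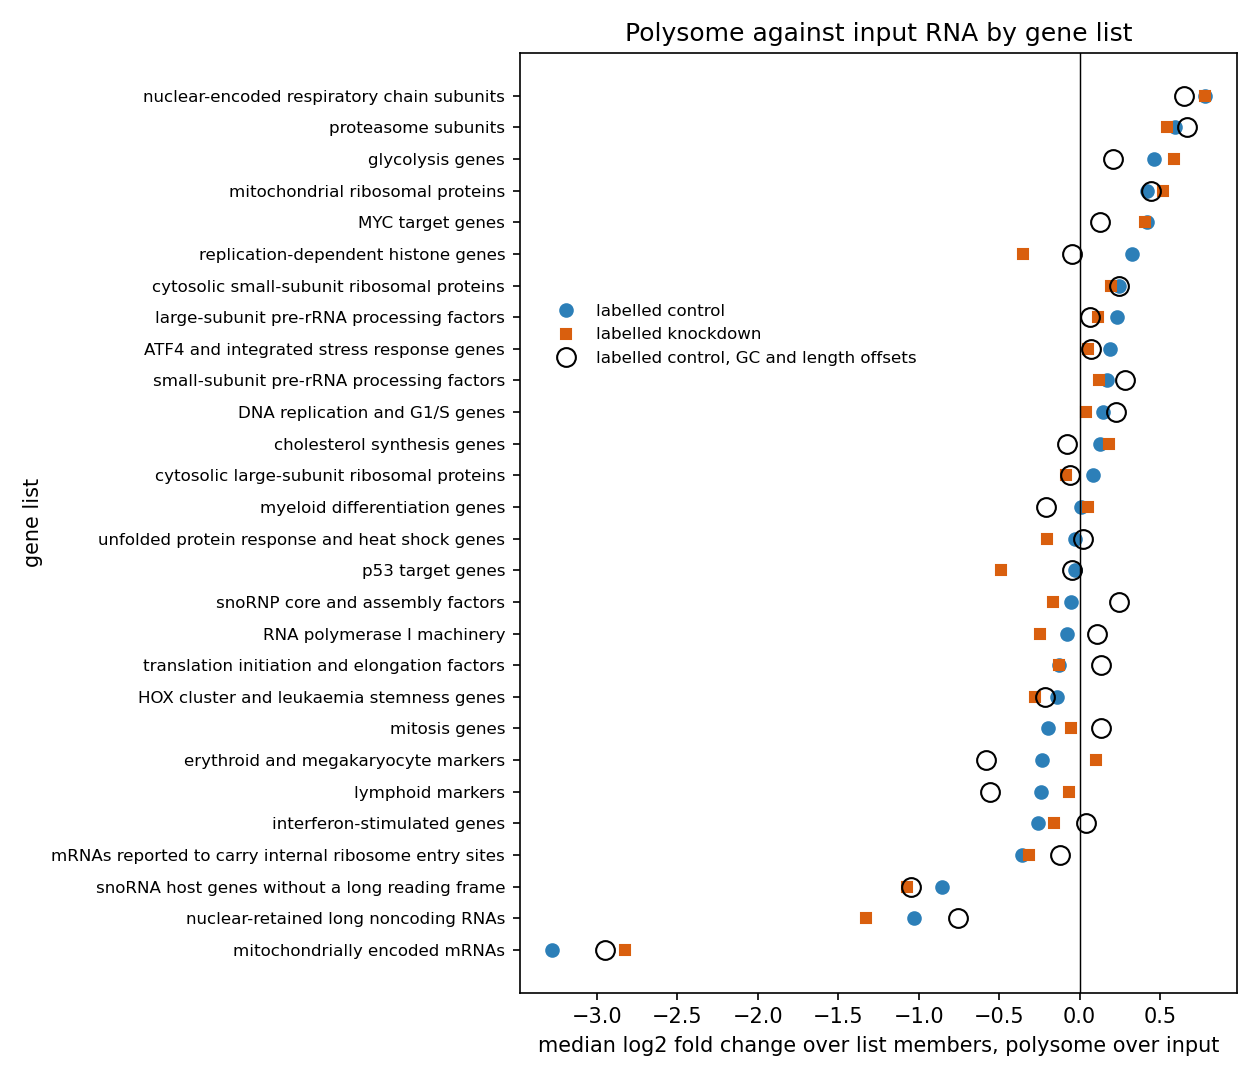
Median log2 fold change of polysome over input RNA for the members of each of the 28 gene lists, in libraries labelled control (filled circles), labelled knockdown (squares) and labelled control after GC and length offsets (open circles). Nuclear-encoded respiratory chain subunits had medians of 0.78, 0.78 and 0.65, and mitochondrially encoded mRNAs medians of -3.27, -2.82 and -2.95.

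In the libraries labelled knockdown, a comparison added after the FBL counts were seen, 2343 genes were higher in polysome RNA and 2354 lower. Of these, 3582 were also called in the libraries labelled control, all 3582 in the same direction. Independent lists would share 684 in the same direction. The 2 comparisons have no library in common, but each gene has the same estimate of spread in both, so 684 is a low baseline. Over all 16503 genes the log2 fold changes of the 2 comparisons correlated at 0.39. Respiratory chain subunits rose in 52 of 74 cases (median 0.78, and adjusted p = 0.112 with an estimated correlation), mitochondrial ribosomal proteins in 37 of 77 (0.52, and adjusted p = 0.043 with an estimated correlation) and proteasome subunits in 18 of 31 (0.54, and adjusted p = 0.166 with an estimated correlation). The snoRNA hosts fell in 13 of 19 (-1.07, and adjusted p = 0.031 with an estimated correlation). With the lysate as a block too, the estimated correlation gave an adjusted p of 0.400 for both the mitochondrial ribosomal proteins and the snoRNA hosts. The smallest of any list in that fit was 0.379, at fewer residual degrees of freedom, so these losses decide nothing. With the lysate block and the preset correlation, small-subunit pre-rRNA processing factors passed here (adjusted p = 0.023, camera) but not in libraries labelled control (0.085). The difference between the labels did not pass for them (0.555). Mitochondrially encoded mRNAs fell in 12 of 13 (-2.82, and adjusted p = 0.351 with an estimated correlation), and polysome knockdown 2 held 0.638% of its counts in them, against 0.157% to 0.271% in the other polysome libraries. CLSPN and ZNHIT6 were picked for their large increases in libraries labelled control, so smaller changes in libraries labelled knockdown were likely beforehand. CLSPN had a log2 fold change of 1.04 (SE 0.51, adjusted p = 0.159) and ZNHIT6 of 0.34 (SE 0.59, adjusted p = 0.728), so neither was called there, and without a block the difference between the labelled groups did not pass for either. With the lysate as a block that difference passed for CLSPN (-2.69, adjusted p = 0.026), and CLSPN was itself called in these libraries, at 0.99 (adjusted p = 0.020), as was FBL, at 0.98 (adjusted p = 1.6e-08, from 0.332 without it). The counts fell to 1572 higher and 1105 lower without input knockdown 1, to 1732 and 1396 without input knockdown 2, and to 1454 and 1199 with GC and length correction, which kept 2012 of the 4697 calls, 2002 of them in the same direction.

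The change between input and polysome RNA followed the GC content of the transcripts. Over 13085 protein-coding genes, which are not independent replicates, the Spearman correlation of the log2 fold change with GC content was 0.57 in libraries labelled control and 0.52 in libraries labelled knockdown, and with exon length -0.10 and -0.13. In the 1311 genes poorest in GC (median 37.0%) the median change was -0.83 in libraries labelled control, and in the 1308 richest (64.4%) it was 0.76. Between labelled knockdown and control the correlation with GC content was 0.01 in input and -0.07 in polysome RNA, where the median change in the 1308 genes richest in GC was -0.21. Over 79 ribosomal protein genes it was -0.33 in polysome RNA and -0.37 for the difference between the fractions.

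**Figure D4:**
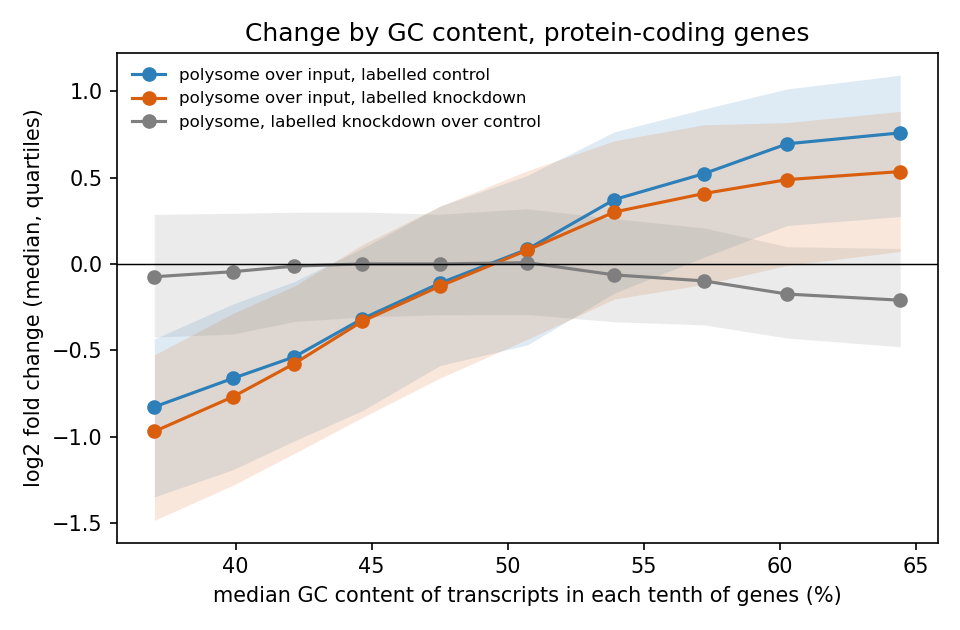
Median log2 fold change (points) and quartiles (shading) of protein-coding genes in 10 bins ordered by transcript GC content in percent, for polysome over input RNA in libraries labelled control and labelled knockdown and for labelled knockdown over control in polysome RNA. In libraries labelled control the median goes from -0.83 to 0.76 from the poorest to the richest bin.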

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

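Counts of calls between labelled knockdown and control depended strongly on the processing, and polysome against input calls depended on GC and length correction. The correction for GC content and length and the filter at 10 CPM were chosen after seeing the data, as was the comparison in libraries labelled knockdown. Over named genes, 1534 values under an alternative stayed on their side of the threshold, 182 lost a call, 43 gained a call and 0 changed direction with a call in either fit. Over gene lists these numbers were 2516, 112, 172 and 8. The cause of each change was not tested. Fewer libraries or residual degrees of freedom lower the power of the fit of 4 libraries and of the fits that leave a library out. In the latter the lone library of a group is assumed to vary like the others. Lower power alone does not describe the fit of 4 libraries. There, genes at an unadjusted p under 0.05 (edgeR) went from 744 of 16503 to 1619 of 15543 in input RNA. In polysome RNA they went from 2987 of 16503 to 1582 of 14444. Whether the spread shared by all 8 libraries is too wide for input and too narrow for polysome RNA was not tested. Depth was 22.2 M to 43.1 M counts per library.

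In input RNA, where no gene was called, DESeq2 gave 40 higher and 36 lower, limma-voom 3 higher, and no filter 64 and 19. In polysome RNA (41 higher and 104 lower) DESeq2 gave 508 and 695, limma-voom 75 and 222, no filter 531 and 586, upper quartile normalization 48 lower, the 4 libraries alone 0 and 0, GC and length offsets 0 and 0, and the filter at 10 CPM 194 and 132. For the difference between the fractions DESeq2 gave 2 and 8, and no filter 15 and 40. For polysome against input RNA GC and length offsets gave 1327 and 1109 in control and 1454 and 1199 in knockdown libraries, from 2720 and 2090 and from 2343 and 2354.

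Leaving out each library in turn gave 0 to 0 higher and 0 to 1 lower in input RNA, 0 to 392 higher and 0 to 1063 lower in polysome RNA, and 0 to 11 higher and 0 to 44 lower for the difference. In control libraries it gave 1748 to 3014 higher and 1367 to 2957 lower, and in knockdown libraries 1572 to 2292 higher and 1105 to 2961 lower. FBL kept an adjusted p above the threshold between the labels in every alternative.

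With the replicate number as a replicate block, input RNA gave 53 higher and 13 lower, polysome RNA 342 and 711, with 145 of the 145 genes kept, and the difference 1 lower. With GC and length offsets and the replicate block together these were 38 and 21, 405 and 389 (140 of the 145 kept), and 1 lower. The number 1 minus number 2 differences correlated at 0.47 between input control and input knockdown and at 0.18 between polysome control and polysome knockdown, but with 2 numbers the libraries share only a number across labels. FBL itself differs by number, and whether the number also carries a technical batch was not tested. With the lysate as a replicate block the difference gave 9 lower, and with GC and length offsets added 1 higher and 6 lower. Apart from the values given with each comparison, the only other list call the lysate block alone changed was DNA replication and G1/S genes in knockdown libraries (adjusted p = 0.101).

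List tests changed direction in 8 cases, each with a call in only one of the fits compared. The p53 targets in input RNA were at a median of 0.10 without input control 2 and at -0.56 without input control 1. Mitochondrially encoded mRNAs without polysome knockdown 2 were at -0.74 in polysome RNA and at -0.78 for the difference, and without polysome knockdown 1 at 1.17 and 1.13. Translation factors in control libraries were at 0.13 with GC and length offsets and either replicate block. Mitosis genes in knockdown libraries were at 0.16 with GC and length offsets and at 0.14 and 0.13 with the number or the lysate block added.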

Other observations

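Translation factor mRNAs moved both ways between input and polysome RNA, as the following genes, chosen after their values were seen, show. The tests of sequencing depth, of label-following differences, of the replicate number with the group in the fit and of GC content in ribosomal protein mRNAs were chosen after the result was seen, and the GC and length correction was added after seeing the data, with its bounds set before its outcome was known. The other tests here were chosen before their result was seen. In libraries labelled control the poly(A)-binding protein PABPC1 had a log2 fold change of -2.82 (SE 0.11), the initiation factor subunit EIF3H -1.88 (SE 0.11) and the helicase EIF4A2 -1.38 (SE 0.12). EEF1G of the elongation factor 1 complex stood at 1.81 (SE 0.19), the scaffold EIF4G1 at 1.26 (SE 0.10) and EIF3B at 1.13 (SE 0.10). All 6 had adjusted p from 1.6e-06 to 9.2e-05 (edgeR) and the same sign in libraries labelled knockdown, with PABPC1 at -2.70 and EEF1G at 2.50. With GC and length correction PABPC1 was at -2.99, EIF3H at -1.29, EIF4A2 at -0.68, EEF1G at 1.54, EIF4G1 at 0.72 and EIF3B at 0.64, each still called. EEF1G and PABPC1 have pseudogenes that share sequence. Over the 47 translation factors the Spearman correlation of the change with GC content was 0.61 in control and 0.67 in knockdown libraries, and 0.17 and 0.25 after the correction.

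Among ribosomal protein mRNAs, RPS6 (-1.12, SE 0.08), RPL12 (-1.17, SE 0.10) and RPL6 (-1.01, SE 0.09) were lower in polysome RNA of libraries labelled control, and RPL32 (0.97, SE 0.10) and RPL35 (0.93, SE 0.07) higher. A hypothesis is that this spread follows base composition and may in part be made by library preparation. Over 79 ribosomal protein genes the Spearman correlation of the change with GC content was 0.47, against 0.57 over all protein-coding genes. After the correction RPL35 was at 0.17, no longer called, while RPS6 (-0.61), RPL6 (-0.55), RPL12 (-1.41) and RPL32 (1.17) stayed called. The correlation over the 79 genes was then -0.22, so the correction went past 0 in this class and its values there are rough.

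FBL was the same in both labelled arms and about 65% to 67% lower in each library numbered 2. Depth of the number 2 libraries is argued against, because in the groups where that library is the deeper of the pair its raw FBL count was still at most 0.46 of the other. That the number marks which cultures carried the FBL hairpin is a candidate explanation that no value here decides. Ordered from the largest mean decrease in number 2, FBL ranked 6 of 8159 genes. In a fit with group and replicate number FBL ranked 1 of 16503 genes by p for number (log2 fold change -1.57, SE 0.05). Both ranks restate the observation that prompted the test. FBL was not alone in that fit, which called 300 genes for number and 1110 for label, counting the input and polysome libraries of a single lysate as separate samples. An exchange of control 2 and knockdown 1 gives the same FBL values and stays open: parting the 4 input libraries by number called 0 genes, as did the other 2 ways of parting them (unadjusted p under 0.05 in 323 genes by number, 744 by label and 25 crossed), but that test leaves the label-following differences in the spread and so decides nothing. The knockdown minus control difference at number 1 correlated at 0.51 with that at number 2 over 8159 input genes. After an exchange the printed labels would part the libraries by true replicate, and replicate differences would correlate in this way too. The correlation therefore cannot argue against an exchange, and no biological explanation was tested.

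For the 145 genes called between the labels in polysome RNA, the median change in the called direction was 0.72 (quartiles 0.63 and 0.93) and 0.59 (0.46 and 0.86) after GC and length correction, a ratio of 0.82 with an SD of 0.16 over genes. None was then called in that fit: the changes were smaller at the same median SE (0.12 both times), all 145 kept their direction, and the smallest adjusted p was 0.052, so GC content may account for part of the pattern and stays open. Without the shallow library polysome knockdown 2 the median change was 0.63, a ratio of 0.87 (SD 0.10). These genes were picked in a fit that held this library, and a call needs the libraries of a group to lie close. A similar change without it was therefore likely beforehand, so the ratio cannot decide, and this library stays open as a source. The labelled parting of the 4 polysome libraries gave 145 calls and the others at most 1, and 1 of the 3 partings gave as many, a number too small for a share under 0.05. A difference between the labelled arms stays open and, given the FBL counts, cannot be tied to FBL.

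For the 8 gene lists that differed between polysome and input RNA in control libraries, GC content and length are argued against as the whole source for 7, since a share of 0.875 of the lists passed in the same direction after the correction, for example respiratory chain subunits at a median of 0.65 from 0.78. MYC targets went to 0.12 from 0.42 (adjusted p = 0.089, and 0.026 with the lysate as a block in the corrected fit), so GC content may account for much of that list. In that blocked fit all 8 lists passed in the same direction. Abundant RNAs taking up counts were not decided: without mitochondrially encoded genes and the 20 most abundant genes the share was 1 (7 of 7 lists), but the removal moved the log2 fold change of the other genes by a median of 0.0014, and scaling takes up a shift common to all genes, so the lists had to keep passing. Translation of GC-rich mRNAs and a GC bias of libraries made from less RNA would both give the overall trend, and a difference between polysome-bound and other RNA, which the design names, stays open beside them for the 7 lists.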
